A study of Bos taurus with 9 samples.

How the data were processed

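The libraries came from cattle (Bos taurus) oocytes. Per the labels' protocols, cumulus-oocyte complexes were aspirated from follicles of 2 to 4 mm in ovaries from a slaughterhouse and matured in vitro in groups of 25 in droplets of 90 µL. Maturation lasted 24 h in medium with dichloroacetate, with iodoacetate or with neither. The cumulus cells were then removed, and only oocytes with a first polar body, the sign of completed nuclear maturation, were kept. Each library was made from a pool of 5 oocytes, about 0.1 ng of total RNA, with the SMART-Seq HT kit, which copies polyadenylated RNA into full-length cDNA and amplifies it, followed by Nextera XT library preparation and 100 bp paired-end sequencing on a NextSeq instrument. The labels list several doses of each compound, from 0.1 to 5 mM for dichloroacetate and from 0.1 to 5 µM for iodoacetate, and do not say which of them the sequenced oocytes received. Dichloroacetate is known as an inhibitor of the pyruvate dehydrogenase kinases and iodoacetate as an inhibitor of the glycolytic enzyme glyceraldehyde-3-phosphate dehydrogenase.

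The authors deposited 1 table of read counts per gene, whole numbers that had not been normalized. Per the submitters' processing notes, the tools used were Trim Galore, cutadapt, STAR, featureCounts and DESeq2. Their versions, the genome build and the annotation are not given in the sources used here. Neither is the counting mode, so reads from near-identical gene copies or from overlapping genes can be divided between them in a way that is not known. The kit does not mark strand, so antisense transcripts are not told apart from their partners. The kit has no molecular identifiers, so counts include copies made during amplification, and the amplification from 5 oocytes adds to the spread between libraries.

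The table held 15978 genes under Ensembl identifiers. All 9 columns were used, and each was assigned to its sample by the sample's title. The files do not pair the identifiers with gene names, and 0 identifiers matched a symbol in the gene table supplied with them. The 24 gene lists set out for pyruvate, energy and redox metabolism, chromatin modifiers, oocyte genes and markers of other cell types were therefore not analysed here, and neither were the genes of glyceraldehyde-3-phosphate dehydrogenase and the pyruvate dehydrogenase kinases or the share of mitochondrial counts. No genome was used.

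The groups were taken from the treatment given in the labels, with 3 libraries each. The replicate numbers only name the libraries of a group in the order of the samples. The labels do not say that they pair libraries between groups, and no block was fitted. Nothing in the labels says that the pools of a group came from separate maturation runs or separate collections of ovaries, so the p-values measure only the spread between these libraries, which may be partly technical. Before libraries were averaged, the counts of each pair within a group were compared by a chi-square test over genes, and every pair differed by more than sampling noise (chi-square per degree of freedom from 14.8 to 52.8), so no library was counted as a copy of another. This test covers counting error only, and separate amplifications of the same pool would differ too, so it does not show that the libraries are separate biological samples.

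Differences between groups were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, the default expression filter with the groups, and the robust quasi-likelihood test. One model with a coefficient per group was fitted to all 9 libraries, so that the 3 comparisons shared 1 estimate of the spread. The filter kept 12016 genes and left out 3962, among them 4 with no count in any library. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and an adjusted p under 0.05 counted as a difference. Standard errors of log2 fold changes were computed from the quasi-likelihood F statistic, and 95% confidence intervals of fold changes from the same fit. Expression values are CPM, the counts scaled to a common library size after TMM normalization. Principal components and differences between group means used log2 CPM with a prior count of 2. Library totals, numbers of detected genes and shares of the most abundant genes were compared by two-sided exact permutation tests, for which 3 libraries against 3 give a smallest p of 0.1.

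Both treated groups were compared with the same 3 control libraries. The agreement of their fold changes was therefore set beside 100 simulations of unchanged groups against shared controls. For lists of genes, 20 such simulations were tested with edgeR and DESeq2 and lists of the observed sizes were taken by smallest p. These list simulations were added after the result was seen. The controls could not be divided into parts that each keep 2 libraries, so part of any excess over the simulated values may come from the shared controls.

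The genes to be named were those with an adjusted p under 0.05 and complete separation of the groups. Where fewer than 5 passed, the rule took the 5 with the smallest p in a comparison, given as values only. Because the identifiers could not be paired with names, at most 2 higher and 2 lower identifiers are printed per comparison. This rule, the tests and the alternative settings were chosen before the data were examined, except those named as added.

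The alternatives were relative log expression and upper-quartile scaling, DESeq2 1.42.0, limma 3.58.1 with voom and quality weights, no filter on low counts, a filter of at least 50 counts in at least 3 libraries, fits of only the groups compared, a fit without robust estimation, a threshold of 0.1 for the adjusted p, and leaving out each library in turn. Added after the data were seen were a covariate holding the first principal component of the log2 CPM values centred within groups, the removal of the 3 libraries at the high end of that component, and a comparison of all 6 treated libraries with the control. The simulated gene lists, and the tests named so in the closing section, were also chosen after the result was seen.

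The edgeR steps were tested on simulated counts drawn from the means and sizes of these libraries, with 200 genes changed by known factors. At an adjusted p under 0.05, the test found 29.8% of genes changed 2-fold and 84.4% of those changed 4-fold in the simulated comparison of iodoacetate with control, 29.8% and 83% in that of dichloroacetate with control, and 27.4% and 83% in that of iodoacetate with dichloroacetate. The mean number of unchanged genes called was 9.6, 7.2 and 10 in the same order. Each gene was drawn independently, and the p needed to pass the adjustment depends on how many genes change. These shares therefore need not hold for the real comparisons.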

Results

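Messenger RNA was measured by RNA sequencing in mature bovine oocytes, the stage ready for fertilisation, after in vitro maturation with iodoacetate, with dichloroacetate or with neither compound. Each group had 3 libraries, and each library was a pool of 5 oocytes. The series asks how a change in pyruvate metabolism during maturation alters the transcripts held by the oocyte. Both compounds are small halogenated acetates. Iodoacetate is known to block a step of glycolysis upstream of pyruvate, and dichloroacetate is known to favour the entry of pyruvate into the mitochondrial citric acid cycle.

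The libraries held similar numbers of reads and genes. The iodoacetate libraries had 8109768, 9454723 and 9344072 counts in all, the dichloroacetate libraries 8870832, 9077383 and 7776877, and the control libraries 9682862, 9249890 and 9834849. Genes with at least 1 count numbered 15288 ± 41.4 with iodoacetate, 15282 ± 203 with dichloroacetate and 15335 ± 14.8 in the control (SD, n = 3 each). The most abundant gene took 2.15% to 3.58% of the counts and the 10 most abundant genes together 7.63% to 10.3%. None of 12 exact two-sided permutation tests of these measures between groups passed correction, with a smallest adjusted p of 0.6. None could pass, since the smallest unadjusted p in this design is 0.1. Total counts with dichloroacetate and detected genes with iodoacetate reached that p against the control, with every treated library below every control library. Spearman correlations of counts across genes lay between 0.956 and 0.977 for all pairs of libraries.

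The oocytes did not separate by treatment along the main direction of variation. The first principal component held 30.8% of the variance and placed library 2 of each group above the other libraries of its own group. The second component held 16.1%, and on it each control library lay above all 3 iodoacetate libraries. The distance between group means, as the mean squared log2 difference over genes, was tested by exact enumeration of the splits of the libraries. It was as large in 3 of 10 splits for iodoacetate against control (exact permutation p = 0.3), in 4 of 10 for dichloroacetate against control (exact permutation p = 0.4) and in 9 of 10 for iodoacetate against dichloroacetate (exact permutation p = 0.9). With 10 splits the smallest possible p is 0.1. Each group was also set against the other 6 libraries, over 84 splits. The distance was as large in 8 for the control, 47 for iodoacetate and 70 for dichloroacetate (exact permutation p = 0.0952, 0.56 and 0.833).

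**Figure D1:**
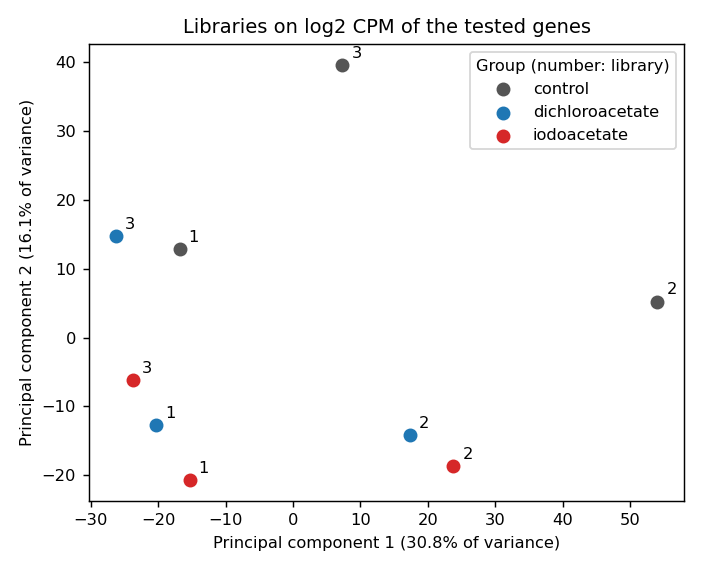
Position of the 9 libraries on the first and second principal components of log2 CPM over the 12016 tested genes, coloured by group and numbered by library. The first component holds 30.8% of the variance and library 2 of each group lies at its high end within that group.

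Iodoacetate was compared with the control to ask which transcripts differ after maturation with a glycolysis inhibitor. The genes with the smallest p-values were lower in the treated oocytes. ENSBTAG00000050012 stood at 205 ± 21.7 CPM with iodoacetate and 438 ± 53.4 CPM in the control (SD, n = 3 each), a log2 fold change of -1.10 with a standard error of 0.20, and its mean with dichloroacetate was 265 ± 68.5 CPM. ENSBTAG00000051456, a transcript of low abundance, stood at 0.488 ± 0.0651 CPM with iodoacetate and 3.01 ± 0.693 CPM in the control (SD, n = 3 each), a log2 fold change of -2.59 with a standard error of 0.46, and its mean with dichloroacetate was 0.991 ± 0.277 CPM. For both genes all 3 treated libraries lay below all 3 control libraries, and in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment both had an adjusted p of 0.374, which does not pass.

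Among the 12016 genes tested, edgeR's quasi-likelihood test called 0 genes higher and 0 lower with iodoacetate, and limma with voom weights also called 0. At an unadjusted p under 0.05 there were 1023 genes, 505 higher and 518 lower, or 8.51% of those tested, where a uniform distribution gives 5%. Of the 10 splits of these libraries into 3 and 3, the real one included, 3 gave as many. The groups did not overlap for 1539 genes, or 12.8%, where random grouping gives 10% on average. Most differences were small, with 95% of absolute log2 fold changes under 0.89 and a median standard error of 0.30. The 392 genes with an estimated difference over 2-fold were mostly of low abundance, and 18 of them were among the 4143 genes with an average log2 CPM above 5, called the more abundant genes from here on. For 56.5% of genes the 95% confidence interval lay within a 2-fold change in either direction, and for the more abundant genes this share was 87.2%.

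The count of called genes depended on the method. DESeq2 called 10 genes higher and 19 lower with iodoacetate. Its calls included ENSBTAG00000050012, with an adjusted p of 0.00667 in DESeq2, while ENSBTAG00000051456 received no adjusted p there. DESeq2 gave an adjusted p to 9160 of 15971 genes in this comparison and to all 15971 in the others, so its counts of calls rest on unlike sets of genes. All 29 genes had the same direction in edgeR with full separation of the groups, a median absolute log2 fold change of 1.09 and an unadjusted p of at most 0.00154. With the main axis of variation within groups added to the edgeR model as a covariate, an alternative chosen after the data were seen, 84 genes were higher and 76 lower. ENSBTAG00000051456 and ENSBTAG00000050012 were among them, with adjusted p-values of 0.0191 and 0.0127 in that edgeR fit. Without control library 3, 1 gene passed as higher and 679 had an unadjusted p under 0.05, and without control library 1 that second number was 1587.

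**Figure D2:**
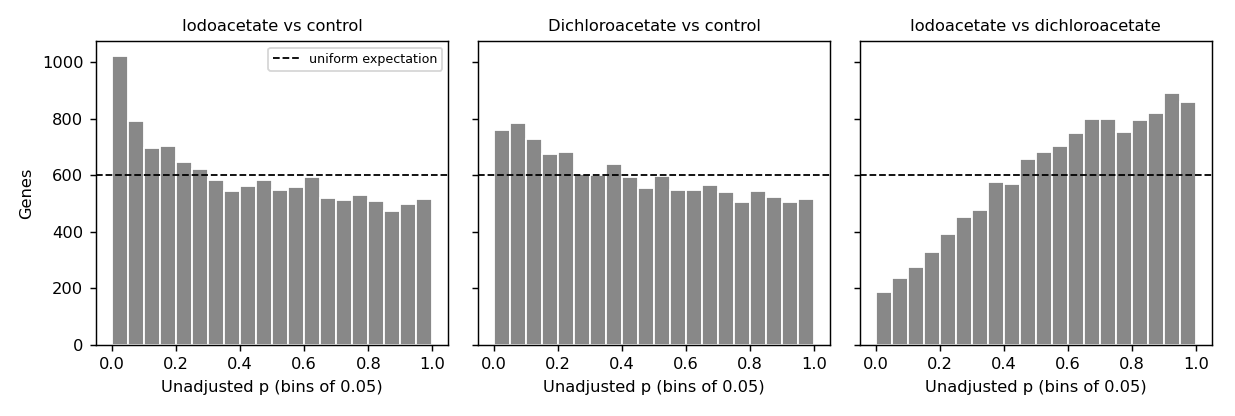
Numbers of genes by unadjusted p-value in edgeR's quasi-likelihood test, in bins of 0.05, for the 3 comparisons, with the number per bin under a uniform distribution as a dashed line. The first bin holds 1023 genes for iodoacetate against control, 759 for dichloroacetate against control and 186 for iodoacetate against dichloroacetate, where a uniform distribution gives 600.8.

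Dichloroacetate was compared with the control to ask which transcripts differ after maturation with a compound that favours pyruvate oxidation. The genes with the smallest p-values differed in both directions. ENSBTAG00000012659 stood at 63.1 ± 10.9 CPM with dichloroacetate and 34.2 ± 0.756 CPM in the control (SD, n = 3 each), a log2 fold change of 0.88 with a standard error of 0.20. ENSBTAG00000051399 stood at 3.41 ± 0.378 and 0.961 ± 0.164 CPM, a log2 fold change of 1.82 with a standard error of 0.44. ENSBTAG00000024431 stood at 32.5 ± 11.1 and 70.6 ± 2.07 CPM, a log2 fold change of -1.12 with a standard error of 0.26, and ENSBTAG00000054102 at 22.8 ± 7.81 and 52.7 ± 11.7 CPM, a log2 fold change of -1.21 with a standard error of 0.29. The iodoacetate means of all 4 genes lay between those of the other groups, at 51.4 ± 4.19, 2.95 ± 1.52, 50.5 ± 14.3 and 38.1 ± 8.62 CPM in the same order. The genes were chosen for differing between dichloroacetate and control, so another group tends to lie between in any case. The dichloroacetate and control libraries did not overlap for any of the 4 genes, and each had an adjusted p of 0.756 in edgeR's quasi-likelihood test, which does not pass.

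With dichloroacetate, edgeR's quasi-likelihood test called 0 genes higher and 0 lower among the 12016 tested, and DESeq2 and limma with voom weights also called 0. At an unadjusted p under 0.05 edgeR gave 759 genes, 371 higher and 388 lower, or 6.32% of those tested. The groups did not overlap for 1299 genes, or 10.8%, where random grouping gives 10% on average. For 57.1% of genes the 95% confidence interval lay within a 2-fold change, and for the more abundant genes this share was 88.7%. An estimated difference over 2-fold was found for 331 genes, of which 6 were among the more abundant. Without dichloroacetate library 1 the number at an unadjusted p under 0.05 was 417, without control library 1 it was 1470, and without control library 3 there was 1 gene that passed as higher.

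**Figure D3:**
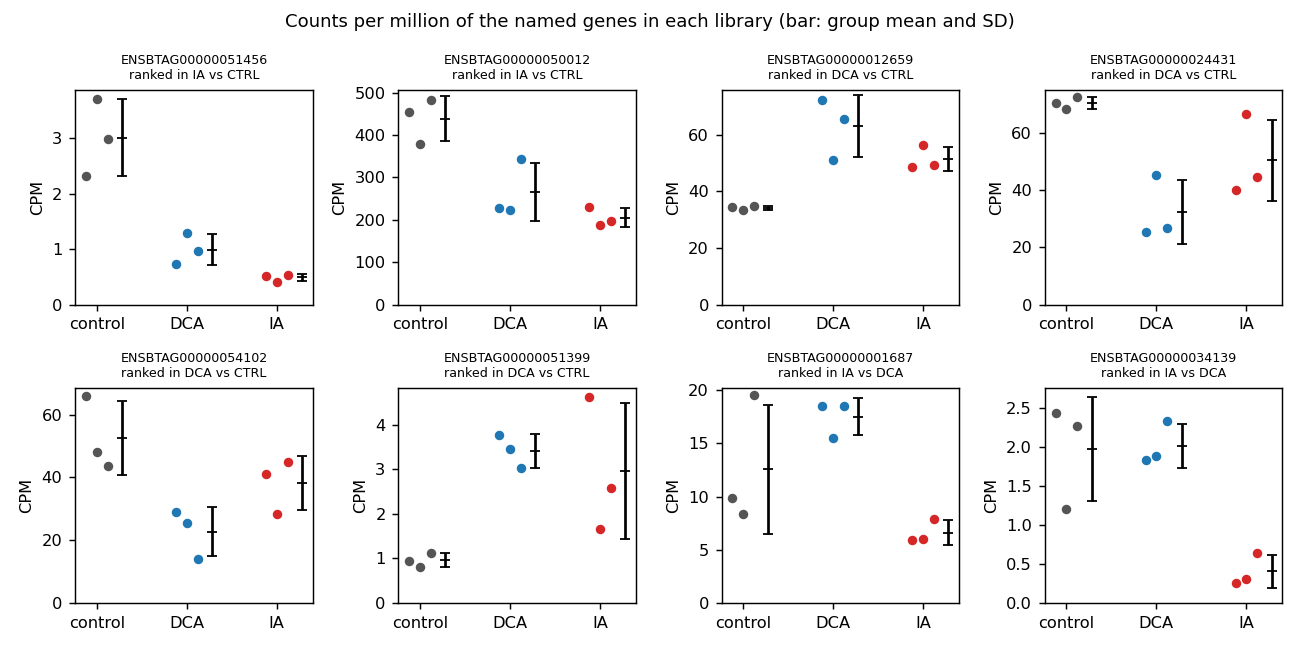
Expression in CPM of the 8 named genes in each library, with the group mean and SD (n = 3) as a bar beside the points. In each panel the libraries of the groups for which the gene was named do not overlap, and none of the 8 genes passed the adjusted p threshold in edgeR's quasi-likelihood test.

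Iodoacetate and dichloroacetate were compared directly, since both are halogenated acetates that act at different steps around pyruvate. The labels do not state the dose of either compound in the sequenced oocytes, and the doses they list are in different ranges, so the comparison is not one of matched doses. ENSBTAG00000001687 stood at 6.62 ± 1.14 CPM with iodoacetate and 17.5 ± 1.74 CPM with dichloroacetate (SD, n = 3 each), a log2 fold change of -1.40 with a standard error of 0.32. ENSBTAG00000034139 stood at 0.404 ± 0.209 and 2.01 ± 0.280 CPM, a log2 fold change of -2.25 with a standard error of 0.53. Control means were 12.6 ± 6.08 and 1.96 ± 0.665 CPM. The treated groups did not overlap for either gene, and edgeR's adjusted p was 0.99982 for both, which does not pass.

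Between the compounds, edgeR's quasi-likelihood test called 0 genes in either direction, and DESeq2 and limma with voom weights called 0. At an unadjusted p under 0.05 there were 186 genes, 74 higher and 112 lower with iodoacetate, or 1.55% of those tested and fewer than the 5% of a uniform distribution. Without dichloroacetate library 2 that number was 288. The groups did not overlap for 570 genes, or 4.74%, where random grouping gives 10% on average. Shares this low do not show that the compounds act alike, since an unpaired comparison finds too few genes if libraries were matched between groups. For 65.1% of genes the 95% confidence interval of the difference lay within 2-fold, and for the more abundant genes this share was 96.5%. Larger differences stay possible for the remaining genes, since the interval of each extends past 2-fold.

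The differences of both treated groups from the control went in the same direction for most genes. The log2 differences from control correlated across genes with r = 0.722, where unchanged groups simulated against shared controls gave 0.492, with a range of 0.464 to 0.519 over 100 simulations. Genes are not independent replicates, so no p-value is attached to this correlation. These simulations and those of gene lists below drew each gene independently. In the data 1 axis held 37.1% of the variance within groups, so the simulated ranges may be too narrow. The covariance was 0.115 against a simulated 0.0662, a difference of 0.0483. With libraries taken as unpaired, the spread of the control libraries alone puts 0.0788 into the covariance, above the simulated value. This leaves a difference of 0.0358. The sign was the same for 79.3% of genes, against 66.5% in the simulations. Of the genes at an unadjusted p under 0.05, 200 were higher in both comparisons and 211 lower in both, and 0 went in opposite directions. In 20 simulations of unchanged groups with shared controls, lists of those sizes shared a mean of 117 higher genes (range 101 to 134) and 89.9 lower genes (range 68 to 112), and 1.9 went in opposite directions. Independent lists would share 15.6 and 16.7, a value that leaves out the shared controls. Part of this excess may come from the 3 control libraries that both comparisons share.

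**Figure D4:**
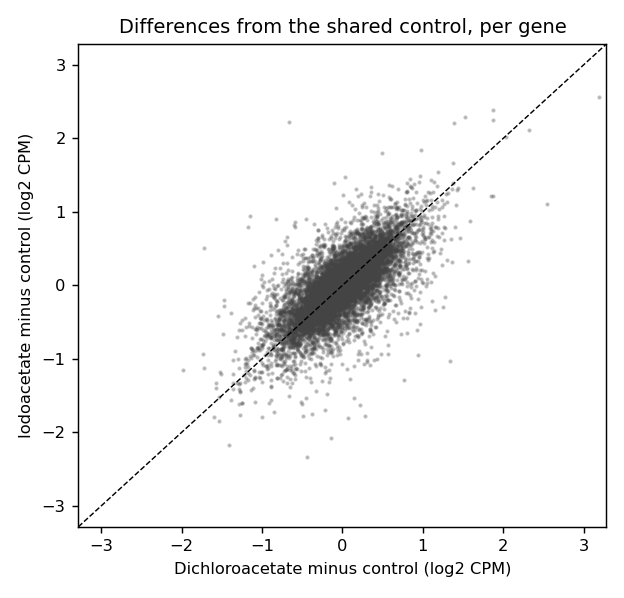
Difference from control in log2 CPM for each of the 12016 tested genes, with dichloroacetate on the horizontal and iodoacetate on the vertical axis and the line of equal difference dashed. The cloud of genes follows the diagonal with r = 0.722, against 0.492 for simulated unchanged groups that share their controls, with each gene drawn independently.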

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

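The fit with a covariate, the removal of 3 libraries and the pooling of both treated groups were chosen after the data were seen. The counts of 0 called genes held in all 3 comparisons under both other scalings, voom with quality weights, both other filters, fits of only the groups compared, no robust estimation and an adjusted p threshold of 0.1. DESeq2 called 10 genes higher and 19 lower with iodoacetate than in the control. With the first axis of variation within groups as a covariate, 84 were higher and 76 lower with iodoacetate, 28 of the 29 DESeq2 genes among them, and 1 was higher with dichloroacetate. Leaving out 1 library gave 0 to 1 genes higher with iodoacetate and 0 to 1 higher with dichloroacetate than in the control, the 1 in both cases without control replicate 3, and 0 in every other count. Leaving out the 3 libraries at the high end of the axis gave 0 calls. The cause was not tested for DESeq2 or for control replicate 3. At an unadjusted p under 0.05, the covariate moved 1023 genes to 1905 with iodoacetate and 759 to 1689 with dichloroacetate (1205 with voom). Between the compounds it moved 186 to 348, and voom gave 296, all of 12016 genes tested. There, no filter gave 308 of 15974, the stricter filter 103 of 8312 and the fit without the 3 libraries 388 of 11917. The correlation of the fold changes of both treatments was 0.492 when simulated from unchanged groups, and ranged from 0.632 without dichloroacetate replicate 1 to 0.812 without control replicate 1. Neither the removal of mitochondrial genes nor the gene list tests were run, since the identifiers have no names here. No paired analysis was run, because the labels give no replicate numbers shared between groups, so all counts here come from fits that take the libraries as unpaired. If libraries were handled in sets, a candidate described below, such fits may miss differences, and the counts of 0 do not show that groups are alike. With iodoacetate against control the median standard error was 0.22 for genes above 5 in average log2 CPM and 0.30 over all genes, and whether depth or amplification sets this was not tested.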

Other observations

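The counts over other splits of the libraries, the sets formed from title numbers, the simulations and splits of the covariate fit, the simulated gene lists, and the comparison with the spread of the controls are tests chosen after the result was seen. The tests by thinning and by loess curves were set out before their results.

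The first pattern was an axis of variation within the groups. After each group's mean was removed, 1 axis held 37.1% of the remaining variance, and library 2 of each group stood at its high end, with scores of 29.8 for iodoacetate, 28.2 for dichloroacetate and 41.7 for the control. In the same order, these libraries had 8.25%, 7.99% and 7.63% of counts in their 10 most abundant genes. Each was the lowest share of its group, and the cause of this was not tested. Differences in depth and a trend with expression level are argued against, since the axis held 36.8% with all libraries thinned to the smallest total and 36.8% after loess curves were removed. A candidate explanation is that libraries were handled in sets. Sets of 1 library per group can be formed in 36 ways. Only the order of the numbers in the sample titles gave deviations that correlated this highly (mean 0.258 against 0.209 for the next). With these sets, 8 of the 9 libraries correlated best with a library of their own set. Deviations cancel within each group, so this count is not independent of the result over the 36 ways. Pairs in the set of the libraries numbered 2 correlated at 0.325 to 0.445, and pairs in the other sets at 0.113 to 0.247. The labels describe no such sets, this was found and tested on the same data, and no biological explanation was tested.

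A share of small p-values between iodoacetate and control above 5%, and the calls that appeared with a covariate, form the second pattern. Whether the share exceeds chance cannot be told, since 3 of 10 splits of the same libraries, the real one included, gave as many such genes. A trend with expression level as the whole cause is argued against by limma on loess-corrected values, where 8.98% of genes stayed at an unadjusted p under 0.05, against 8.46% before. For the 160 calls made with the axis as a covariate, simulations with such an axis and no group effect gave at most 6 calls, and of the other splits of the same 6 libraries 1 gave 892 calls, 1 gave 58 and the rest at most 3. The split with 892 set iodoacetate libraries 1 and 3 with control library 1 against the others, which parts these 6 libraries along the first principal component, so it points to a structure of the samples and is no clean value for groups without an effect. The other splits that put 1 library of each title-number set on each side gave 0, 1 and 0 calls. Without the covariate they gave 175, 262 and 418 genes at an unadjusted p under 0.05, against the real 1023. For dichloroacetate against control, splits of this kind gave 122, 173 and 387 such genes, against the real 759. Between the compounds they gave 159, 278 and 244, against the real 186. In each comparison these splits are too few to decide, and the sets were found on the same data. Calls made by the covariate itself cannot be told apart from an effect of iodoacetate here. Apart from the axis, the simulations drew each gene independently, and the splits are too few. An effect of iodoacetate on the oocyte transcripts stays open.

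The third pattern is that the fold changes of both treatments went together. Noise of the shared control libraries may account for part of it. The observed covariance was 1.45 times the variance that the spread of the control libraries puts into the control mean. The bound that would have argued against it was 1.5 times, set after the result was seen. If libraries were handled in sets, part of the control spread would cancel in the differences, and this ratio would be too low. The explanations therefore cannot be told apart. All 29 genes that DESeq2 called with iodoacetate had the same direction with dichloroacetate, but the 29 genes of smallest p in simulated unchanged groups with shared controls did so for a mean of 27.4 (range 26 to 29), so the direction alone says little. Their median log2 change with dichloroacetate toward that direction was 0.76 in edgeR. In DESeq2 on 20 simulations it had a mean of 0.56 and a highest value of 0.71, a bound that excludes nothing by itself. The estimates come from unlike methods, and the simulated genes were drawn independently and not matched for the size of their iodoacetate difference. The higher observed value therefore decides nothing. A response common to both compounds stays open, as does a peculiarity of the 3 control pools.

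Other splits of the libraries bear on each count. Splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. All splits take the libraries as exchangeable, and if the sets from the title numbers were real, splits that mix the sets would be no fair values for groups without an effect. The real number of called genes was 0 in each comparison, so 10 of 10 splits gave as many by construction, which tests nothing, and the highest other values were 3 for iodoacetate against control, 0 for dichloroacetate against control and 2 between the compounds. For genes at an unadjusted p under 0.05, 3 of 10 splits gave as many as the real 1023 with iodoacetate (highest other 2385), 4 of 10 as many as 759 with dichloroacetate (highest other 2212) and 9 of 10 as many as 186 between the compounds (highest other 1015). With the axis found again in each split as a covariate, 2 of 10 gave as many calls as the real 160 (highest other 892) and 6 of 10 as many as 1 (highest other 807), in the same order, and between the compounds the real count of 0 again left 10 of 10 by construction (highest other 28). For all 6 treated libraries against the control, edgeR called 0 genes and gave 1366 at an unadjusted p under 0.05, and 6 of the 84 splits gave as many, so chance cannot be excluded. The highest other split, library 2 of each group against the rest, gave 3162 such genes against the real 1366, which points to a structure of the samples. The highest number of calls in any other split was 1147, against the real 0.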
